A study of Mus musculus with 28 samples.

How the data were processed

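RNA from formalin-fixed, paraffin-embedded livers of 6 mice was amplified as cDNA, labelled chemically and hybridized to 28 Agilent mouse arrays on 4 slides: 6 one-colour arrays at 1X and 6 at 1.5X cDNA input, and 8 two-colour arrays at each input. All slides were scanned in 2 sessions. Session 1 held the one-colour 1X and the two-colour 1.5X set and session 2 the other sets, so that within a format input, slide and session cannot be told apart. The authors extracted each array with Agilent Feature Extraction 11.0.1.1. Per the file headers, the deposited scanner tables hold an intensity per spot: the processed signal, background-subtracted and in the two-colour files dye-normalized but not scaled between arrays, and the raw median signals of spot and local background. The deposited two-colour files also hold log10 ratios of Cy5 over Cy3, and the deposited spot flags (unit: other) of 0 or 1 include a call of well above background. The series matrix of the authors was checked against these files: its one-colour columns equal the processed signal, and its two-colour columns the log10 ratio, turned on 8 arrays to phenobarbital over control. For arrays there is no count depth. The signal stands against the negative controls instead: their median was 71.1 in the one-colour 1X and 241 in the one-colour 1.5X set.

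Each array had 62976 spots, of which 3671 were controls, and 55681 distinct probes. Gene names came from matching the RefSeq accessions in the files to a table of assembly GRCm38.p6, used for names only. This named 27235 probes with 20660 symbols, while 28446 probes kept the name or accession in the files. Replicate spots were averaged, and 1 probe per gene name was used, the one with the highest mean one-colour signal. Counts of genes include the names and accessions without a symbol, so they can exceed the number of distinct genes. Over both one-colour inputs 8493 of the 12883 genes tested had a symbol, and in the two-colour 1X set 5658 of 8258.

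One-colour values were the log2 processed signal minus the array's 75th percentile, taken over probes well above background on all arrays of the set. Two-colour values were computed from the median signals, since the tables hold median in place of mean spot signals, with normexp background correction (offset 50), loess (span 0.3) and Aquantile normalization. The value of a mouse was the mean of its Cy3 and Cy5 values, so each mouse was balanced over both dyes. A gene was tested when its probe was well above background on all arrays of at least 1 of both exposure groups. Of the two-colour 1X arrays, 6 were used. Arrays 4 and 8 were left out because their description and their channel labels give each exposure opposite dyes. On arrays 3, 5, 6 and 7 the description and the source names give different mouse numbers, and the description was used, with the source names as an alternative.

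The replicate was the mouse, 3 per group. Exposure groups were compared in each set, and over both one-colour inputs on the mean of the 2 arrays of a mouse. Differences between inputs and between formats were tested on differences within mice, and the inputs were compared with the mouse as a term. All tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The share of probes well above background was compared with an exact sign-flip permutation test. A fold against a group with no array well above background is a lower bound, computed with dim values raised to the lowest level called well above background on that array. Figures used matplotlib 3.10.9 in Python 3.11.15.

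The comparisons, 36 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Of these lists, those with at least 3 members tested entered limma camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Named genes were, over both one-colour inputs, the 10 higher and 10 lower with the largest change among those past the threshold with a symbol and no overlap between the groups (chance gives 10% of genes no overlap), and in each set the 5 higher and 5 lower. A panel of fixed genes and 2 to 4 members of each list with the largest change were added, and for the tests of a difference and of the inputs the 5 higher and 5 lower. Where none passed, the 5 with the smallest p were named.

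Each fit was tested on simulated data with 200 changed genes of known size. At a 4-fold change it found 72.0% of them in the one-colour 1X set, 80.0% in the one-colour 1.5X set, 91.5% over both inputs and 99.0% in the two-colour 1X set. At a 2-fold change it found 0%, 0%, 43.5% and 94.5%. The draws for the two-colour 1X set used the spread with the description's mice. Its median within groups was 0.110, against 0.146 with the source names, so the shares found in that set may be too high. Correlations of fold changes between sets are across genes, which are not independent replicates, and stand beside values from 50 simulated draws without an effect. Alternatives were other normalizations, no filter and a stricter filter, the series matrix values, every probe, blocks for replicate number and slide row, other units of the two-colour fit, both mouse numberings, arrays 4 and 8 included, and each mouse left out. Added after the data were examined were the Cy3 channel alone in both two-colour sets, and the source-name mice in the tests of a difference that use the two-colour 1X set.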

Results

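Livers of male B6C3F1 mice, kept for 16 years as formalin-fixed, paraffin-embedded blocks, were profiled on Agilent mouse expression arrays. The series asked how such archival RNA can be prepared for this platform, with phenobarbital as the test exposure. Phenobarbital, a barbiturate that activates the constitutive androstane receptor (CAR) in hepatocytes, was given at 0.05% in the drinking water for about 4 weeks to 3 mice, and 3 mice served as controls. The RNA of the same 6 mice was measured in 4 sets: one-colour arrays at 1X and at 1.5X cDNA input (6 arrays each), and two-colour arrays at 1X and at 1.5X (8 arrays each). Each set was 1 slide, so every comparison of exposure within a set lay within 1 slide. The mouse was the replicate throughout (n = 3 per group), and the number of arrays limits the precision. In the one-colour sets, 48.0% ± 3.00 (SD, n = 6 arrays) of probes were well above background at 1X and 32.9% ± 3.59 (SD, n = 6) at 1.5X. In the two-colour sets the Cy3 channel had 26.8% ± 3.24 at 1X and 39.4% ± 3.37 at 1.5X, and the Cy5 channel 18.5% ± 3.25 and 4.73% ± 1.67 (SD, n = 8 arrays each).

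The comparison over both one-colour inputs asked what phenobarbital changed in these livers when the arrays of a mouse were averaged. Cyp2b10, the classical CAR target among the cytochromes P450, had the largest fitted increase, with a log2 fold change of 6.21 (SE 0.23, adjusted p = 0.000136). None of its control arrays were well above background, so its increase was at least 23.8-fold. Cyp3a44 rose by a log2 of 3.86 (SE 0.25, adjusted p = 0.00131, at least 3.51-fold), and Cyp2c55, another drug-metabolizing P450, by 3.73 (SE 0.23, adjusted p = 0.00131). Gstm3 and Gstt3, which conjugate electrophiles to glutathione, rose by 2.97 (SE 0.18, adjusted p = 0.00131) and 2.65 (SE 0.19, adjusted p = 0.00226). Por, the reductase that passes electrons to microsomal P450s, rose by 2.39 (SE 0.17, adjusted p = 0.00214).

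Higher genes outside drug metabolism included Orm3, an acute phase glycoprotein (log2 3.93, SE 0.57, adjusted p = 0.0360), and Blm, a DNA helicase of recombination repair (log2 2.78, SE 0.16, adjusted p = 0.00131, at least 3.27-fold). Cdc20 and Ube2c, which act with the anaphase-promoting complex in mitosis, rose by 2.76 (SE 0.34, adjusted p = 0.0204) and 2.41 (SE 0.28, adjusted p = 0.0177). Fndc5, the precursor of irisin, rose by 2.50 (SE 0.23, adjusted p = 0.00736, at least 1.69-fold), and Gadd45b, a stress-response gene, by 2.33 (SE 0.24, adjusted p = 0.00966). Among the lower genes, Col27a1, a fibrillar collagen chain, had a log2 fold change of -1.77 (SE 0.24, adjusted p = 0.0297), and Slc17a2, a phosphate transporter of the sodium-coupled family, -1.54 (SE 0.16, adjusted p = 0.00966). Pcp4l1 (-1.44), Rflna, a filamin-binding protein (-1.42), Afg1l, a mitochondrial ATPase (-1.08), and Rdh9, a retinol dehydrogenase (-0.99), fell as well. Each gene named here for its size had no overlap between the 3 exposed and the 3 control mice, which chance gives for 10% of genes.

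Of the panel fixed in advance, Cyp2c37 (log2 1.58, adjusted p = 0.0229) and Cyp3a11, a main hepatic P450 of the 3A family (1.02, adjusted p = 0.0488), also rose. Cyp2c29 (1.33, adjusted p = 0.0579), Aldh1a1, a retinaldehyde dehydrogenase (1.12, adjusted p = 0.0513), and Ephx1, the microsomal epoxide hydrolase (1.01, adjusted p = 0.0823), did not pass the test. Alas1, the first enzyme of heme synthesis, had 2.02 (adjusted p = 0.131), Cyp1a2 0.70, Cyp7a1 1.15 and Ccnd1 0.96, none of them passing. Nr1i3, which encodes CAR itself, had -0.27 and Cyp8b1 -0.31, also not passing. Without phenobarbital mouse 3 the Cyp8b1 value was 0.12. Cyp2b9, Cyp2b13, Cyp2a5, Cyp4a14, Akr1b7, Gsta1, Ugt1a1 and Abcc4 were not tested in this comparison.

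**Figure D1:**
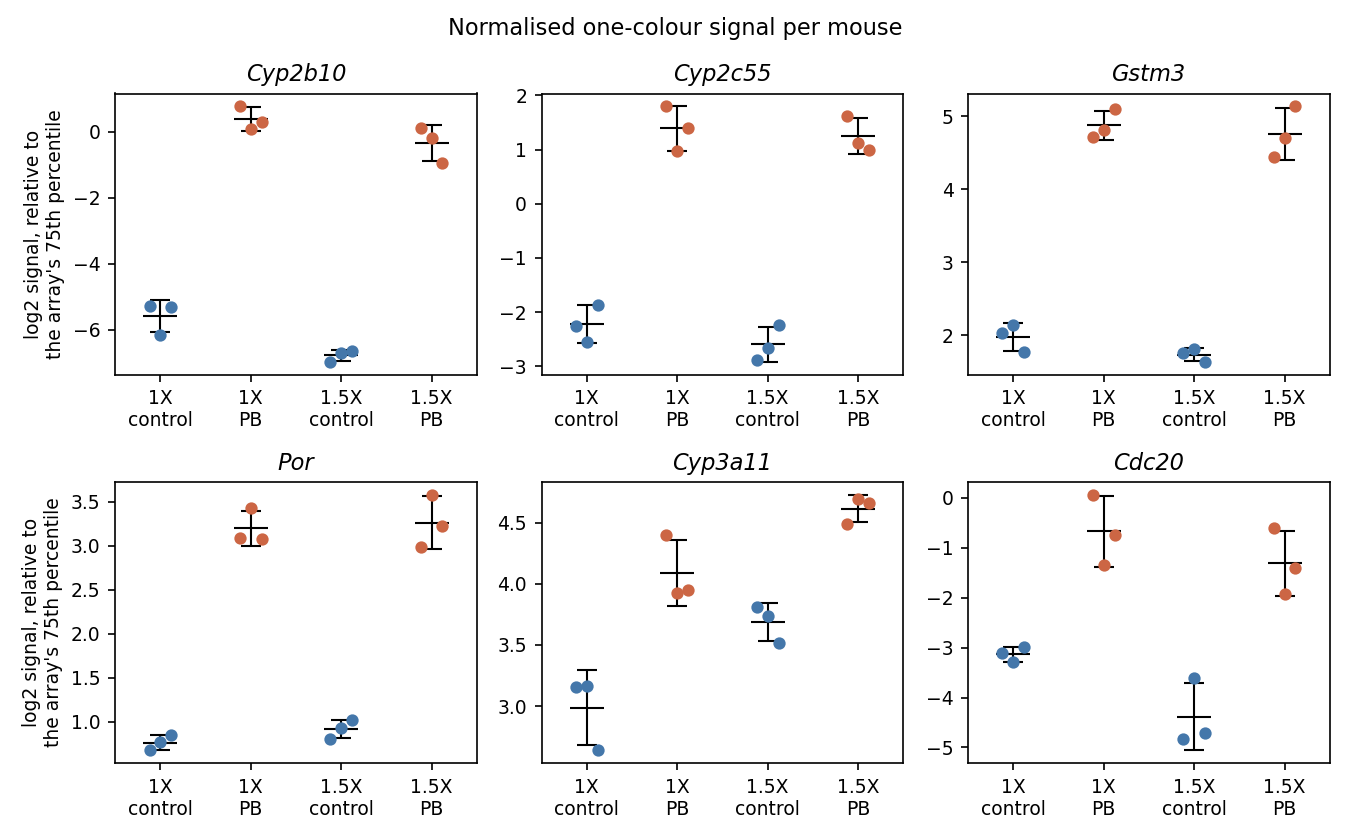
Normalized log2 signal of Cyp2b10, Cyp2c55, Gstm3, Por, Cyp3a11 and Cdc20 in each control (blue) and phenobarbital (orange) mouse at both one-colour inputs; bars show the mean ± SD of 3 mice. The fitted values of Cyp2b10 differed between the groups by a log2 of 5.98 at 1X and 6.44 at 1.5X. No control array held it well above background, so its increases have only lower bounds and the inputs cannot be ranked.

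In total 90 of 12883 genes passed an adjusted p of 0.05 (limma), 80 higher and 10 lower. The count was 16 without control mouse 1, 33 without control mouse 2, 27 without control mouse 3, 16 without phenobarbital mouse 2 and 22 without phenobarbital mouse 3. Without phenobarbital mouse 1 it was 101, with 64 higher and 37 lower. It was 28 without a filter on dim probes, 145 with normexp and quantile normalization, 59 with the series matrix values and 36 with the mouse number as a block. Cyp2b10, Cyp3a44, Cyp2c55, Gstm3, Gstt3, Por and Blm passed whichever mouse was left out. Cyp3a11, Afg1l and Rdh9 no longer passed when any 1 mouse was left out (adjusted p of up to 0.165, 0.133 and 0.173). Orm3 (up to 0.143), Col27a1 (0.132), Pcp4l1 (0.165) and Cyp2c37 (0.0930) lost the call in 5 of the 6 cases, Cdc20 (0.0930), Ube2c (0.0790) and Rflna (0.118) in 4, and Slc17a2 (0.0637) and Gadd45b (0.0643) in 3. Fndc5 lost it only without phenobarbital mouse 2 (0.0610).

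Among the gene lists fixed in advance, the oxidases and reductases that CAR and its relative PXR control moved furthest, with a median log2 fold change of 1.29. Of 28 tested, 12 rose and none fell, and adjusted over the list alone 26 rose and 1 fell. Cyp2b10, Cyp3a44, Cyp2c55 and Cyp2c54 (2.41) had the largest fitted values, and the ranks of Cyp2b10 and Cyp3a44 are unknown because they have only lower bounds. The list's test (limma camera) gave an adjusted p of 3.65e-34 with the preset correlation, and an adjusted p = 0.104 with an estimated correlation. Among 33 phase II conjugation enzymes, 6 rose and none fell, with Gstm3, Gstt3, the sulfotransferase Sult1d1 (1.27) and Gstm4 (1.22) in front. Adjusted over the list alone 16 rose and 1 fell, the median was 0.51, and the list's adjusted p was 3.44e-11 (adjusted p = 0.228 with an estimated correlation).

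Of 15 cell cycle genes tested, Cdc20, Birc5, a survivin that acts at the mitotic spindle (1.82), and Mcm6, a subunit of the replicative helicase (1.33), rose, and none fell. Mcm6 lies outside the rule for named genes and was named after its value was seen. Ccnb1, the mitotic cyclin, had 2.88 (adjusted p = 0.124) and Cenpe, a kinetochore motor, 2.37 (adjusted p = 0.0938), without passing. Adjusted over the list alone 13 rose, the median was 0.99, and the adjusted p was 1.22e-14 (adjusted p = 0.198 with an estimated correlation). Markers of other cell types stood beside this shift with smaller medians: 0.50 for 4 genes of T, B and NK cells and 0.22 for 9 genes of Kupffer cells and macrophages. Of 11 genes with female-biased expression in mouse liver, Cyp3a44, Cyp2a4 (1.84) and Cyp3a16 (1.26) rose and none fell, with 4 rising when adjusted over the list alone. The median was 0.34 and the adjusted p 0.000986 (adjusted p = 0.198 with an estimated correlation). Srxn1, which repairs oxidized peroxiredoxins (0.95), was the 1 of 18 NRF2 targets that rose, and 2 rose adjusted over the list alone. The NRF2 list had a median of 0.31 and an adjusted p of 0.000986 (adjusted p = 0.198 with an estimated correlation).

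Cholesterol synthesis genes lay higher as a list, led by Hmgcs1 (1.05, adjusted p = 0.0523) and Sqle (0.98, adjusted p = 0.0638). None of the 23 passed over all genes and 6 rose adjusted over the list alone, with a median of 0.48 and an adjusted p of 2.98e-05 (adjusted p = 0.461 with an estimated correlation). With normexp and quantile normalization this median was 0.27. Lipogenesis genes lay lower, among them Pnpla3 (-0.96), the desaturase Scd1 (-0.92) and Acly (-0.83). Beside them, genes of adipose tissue, muscle and pancreas had a median of -0.91 (adjusted p = 0.133). Of the 10 tested, 9 were pancreas genes, and Retn, the 1 fat gene, had 0.12. None of the 19 lipogenesis genes passed over all genes and 2 fell adjusted over the list alone, with a median of -0.53 and an adjusted p of 6.68e-05 (adjusted p = 0.461 with an estimated correlation). PPAR alpha and fatty acid oxidation genes had a median of -0.24, with Acot1, an acyl-CoA thioesterase, at -1.04. Of these 24, none passed over all genes and 2 fell adjusted over the list alone (list adjusted p = 0.00264; adjusted p = 0.670 with an estimated correlation). Gluconeogenesis genes had a median of -0.39, with Igfbp1 at -1.25 and Fbp1 at -0.67, and none of 18 passed either way (list adjusted p = 0.00387; adjusted p = 0.461 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.20, with Ndufa4 at -0.41, and none of 42 passed either way (list adjusted p = 0.00161; adjusted p = 0.765 with an estimated correlation). Of 16 male-biased liver genes, none passed over all genes and 5 fell adjusted over the list alone, led by Mup21 (-0.91) and Hsd3b5 (-0.88). Their median was -0.15 and the adjusted p 0.00323 (adjusted p = 0.461 with an estimated correlation).

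Of 22 acute phase genes, Orm3 rose, while Lcn2 (3.44, adjusted p = 0.0544), Orm2 (2.22) and Saa1 (2.21) did not pass. Adjusted over the list alone 7 rose and 1 fell, with a median of 0.45 and an adjusted p of 0.00309 (adjusted p = 0.755 with an estimated correlation). Without phenobarbital mouse 2 the median was 0.08 and the list no longer passed (adjusted p = 0.0628). The neutrophil marker S100a9 stood at 2.08 (adjusted p = 0.236), and the 3 neutrophil genes tested had a median of 0.21. The transporter list passed with a median of 0.18 (adjusted p = 0.0393; adjusted p = 0.755 with an estimated correlation). Its 16 members included the efflux pumps Abcb1a (1.37), Abcc3 (1.07) and Abcc2 (1.04) and the uptake carrier Slco1a4 (1.75), none passing over all genes, with 4 rising and 1 falling adjusted over the list alone. Its call was lost without control mouse 3, phenobarbital mouse 1 or phenobarbital mouse 2 (adjusted p of up to 0.269).

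Extracellular matrix genes passed with a median of 0.16 over 13 genes (Fbln1 0.70, Col6a1 0.56; adjusted p = 0.0273; adjusted p = 0.461 with an estimated correlation). Pericentral genes, which mark hepatocytes around the central vein, had a median of -0.29 over 17 (Cyp1a2 0.70, Glul -0.61; adjusted p = 0.0286; adjusted p = 0.461 with an estimated correlation), with 1 rising and 2 falling adjusted over the list alone. Sinusoidal and vascular endothelium genes had -0.19 over 14 (Vwf -0.62, Stab1 -0.35; adjusted p = 0.0393; adjusted p = 0.612 with an estimated correlation). No gene of these lists passed over all genes, and for matrix and endothelium none passed adjusted over the list alone. The matrix call was lost without control mouse 1 or phenobarbital mouse 1 (adjusted p of up to 0.124), and the pericentral call without control mouse 2 (0.125). The endothelium call was lost without control mouse 1 or 2 or phenobarbital mouse 1 or 3 (up to 0.238).

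The other lists did not pass. Single members that rose were Nr1d2, a repressor of the clock (1.21), among 14 circadian genes with a median of -0.20, and Trib3, a stress-induced pseudokinase (2.10), among 21 ER stress genes. Gadd45b stood among 11 p53 and growth arrest genes with a median of 0.10, and Mpeg1, perforin-2 of macrophages (0.95), among the 9 Kupffer cell and macrophage genes. No member passed among bile acid synthesis genes (12, median -0.18), drug-sensing nuclear receptors and partners (16, -0.11) or genes of periportal hepatocytes (20, -0.10). The same held for hepatocyte secreted proteins (23, -0.06), interferon-stimulated genes (15, -0.14) and immediate early genes (7, -0.20). Medians near 0 were found for 52 ribosomal protein genes (0.01), 29 proteasome genes (0.03) and 15 housekeeping genes (0.02). Markers of other cells had medians of 0.36 for cholangiocytes (5), 0.12 for stellate cells and fibroblasts (10) and 0.08 for red cells (6). Genes of adipose tissue, muscle and pancreas had -0.91 over 10 genes, with Ins2 (-1.60) and the pancreatic elastase Cela2a (-1.01) lowest (list adjusted p = 0.133). Mitochondrially encoded genes had no named probe and were not tested.

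In 2 of these lists the median and the mean differed in sign: ER stress (-0.01 and 0.09) and p53 and growth arrest (0.10 and -0.02). The test of the red cell list pointed down against its positive median. None of the 16 lists that passed held with an estimated correlation. With the preset correlation, another of the 10 splits of the same mice gave 17 lists. The number of lists that passed therefore does not by itself show an effect of the exposure. Without scaling between arrays the median over all genes was -0.23 in place of -0.02, which turned the raw medians of extracellular matrix (-0.05) and transporters (-0.03). The raw medians of neutrophils, housekeeping, p53, proteasome, red cells, ribosomal proteins and stellate cells then turned as well; relative to the median of all genes they did not. With normexp and quantile normalization the median of the transporters was 0.11 in place of 0.18, of T, B and NK cells 0.33 in place of 0.50, of Kupffer cells and macrophages 0.14 in place of 0.22, of neutrophils 0.10 in place of 0.21 and of immediate early genes -0.12 in place of -0.20.

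**Figure D2:**
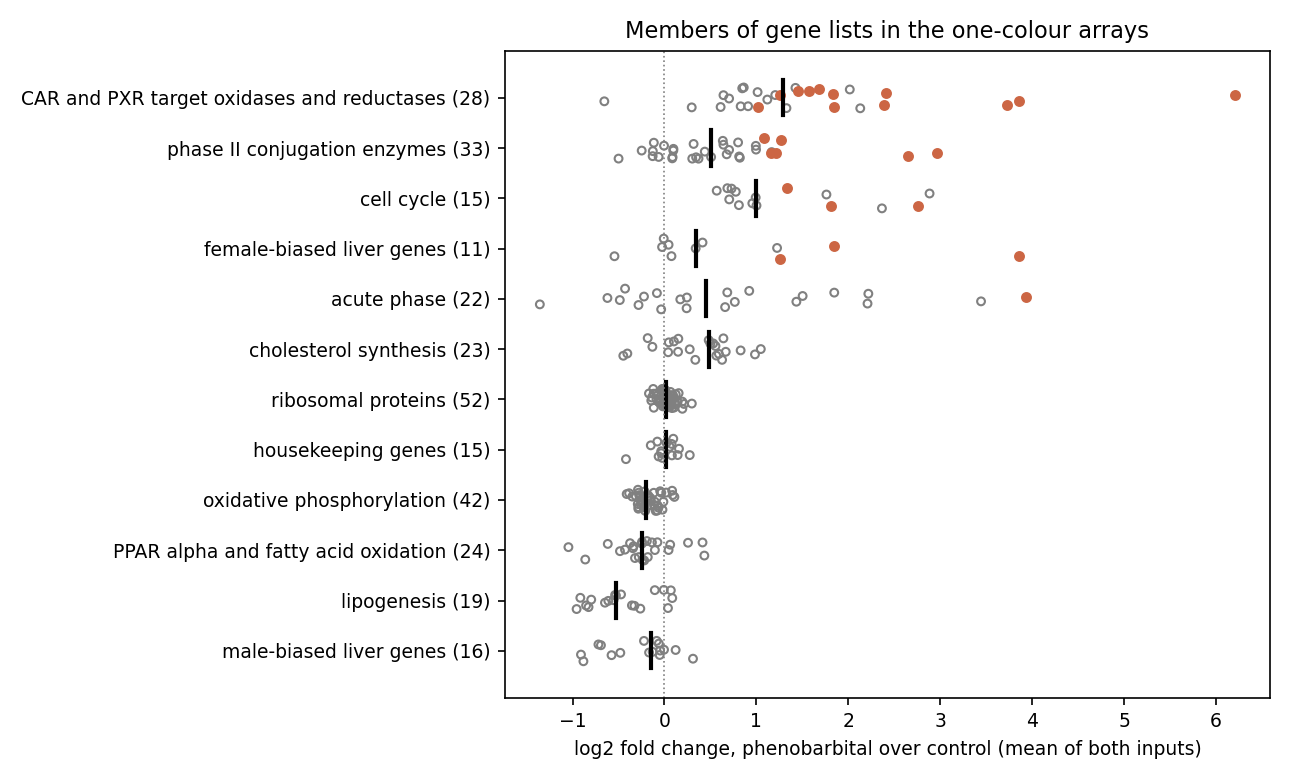
Log2 fold change (phenobarbital over control, mean of both one-colour inputs) of each tested member of 12 gene lists, with filled points for an adjusted p under 0.05 and a bar for the median. The CAR and PXR target oxidases and reductases (median 1.29) and the cell cycle genes (0.99) lie highest, and lipogenesis (-0.53) lowest among the lists that passed.

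At 1X input alone, with 1 one-colour array per mouse, Cyp2b10 rose by a log2 of 5.98 (SE 0.31, adjusted p = 0.000685, at least 30.8-fold), Cyp3a44 by 4.48 (SE 0.24, adjusted p = 0.000685, at least 4.68-fold) and Cyp2c55 by 3.61 (SE 0.28, adjusted p = 0.00508). Moxd1, a monooxygenase of the copper-dependent family, rose by 3.57 (SE 0.33, adjusted p = 0.0127, at least 2.72-fold) and Gstm3 by 2.90 (SE 0.21, adjusted p = 0.00373). Por (2.44, adjusted p = 0.00508) and Akr1b7, an aldo-keto reductase (2.34, adjusted p = 0.0397, at least 2.44-fold), rose too. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was the 1 gene that fell (-1.76, SE 0.21, adjusted p = 0.0388, at least 1.56-fold lower). Cyp2b9 (2.83, adjusted p = 0.0691), Gadd45b (1.79, adjusted p = 0.0691), Cyp2c29 (1.36), Cyp2c37 (1.52), Aldh1a1 (1.24), Cyp3a11 (1.10), Ephx1 (0.94), Alas1 (1.88), Cyp1a2 (0.80), Cyp7a1 (1.13) and Ccnd1 (0.97) did not pass. Neither did Nr1i3 (-0.66) and Cyp8b1 (-0.14), and the latter was 0.23 without control mouse 2 and 0.08 without phenobarbital mouse 3.

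In this set 30 of 18635 genes passed (limma), 29 higher and 1 lower. The count was 5, 18 and 10 without control mouse 1, 2 and 3, and 15, 6 and 7 without phenobarbital mouse 1, 2 and 3. It was 11 with the slide row as a block (11 higher and 0 lower), 3 with the mouse number as a block, 7 without a filter on dim probes and 18 with the series matrix values. Cyp2b10, Cyp3a44 and Gstm3 passed whichever mouse was left out. Cyp2c55 and Por just missed the threshold without control mouse 1 (adjusted p = 0.0516 for both). Moxd1 lost the call without control mouse 1 or 3 or phenobarbital mouse 2 or 3 (up to 0.102), Akr1b7 without any mouse but control mouse 2 (up to 0.207), and Pdk1 without any 1 mouse (up to 0.181).

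At 1.5X input, Cyp2b10 rose by 6.44 (SE 0.28, adjusted p = 0.000841, at least 18.4-fold), Orm3 by 4.10 (SE 0.54, adjusted p = 0.0491) and Cyp2c55 by 3.84 (SE 0.24, adjusted p = 0.00277). Blm rose by 3.54 (SE 0.18, adjusted p = 0.000851, at least 2.78-fold) and Cyp3a44 by 3.24 (SE 0.33, adjusted p = 0.0210, at least 2.63-fold). Of the panel, Gstm3 (3.03, adjusted p = 0.00403), Por (2.35, adjusted p = 0.00651), Gadd45b (2.87, adjusted p = 0.0286) and Cyp2c37 (1.63, adjusted p = 0.0362) rose. Cyp2c29 (1.30), Aldh1a1 (1.00), Cyp3a11 (0.93), Ephx1 (1.08), Alas1 (2.16), Cyp1a2 (0.61), Cyp7a1 (1.17), Ccnd1 (0.94), Nr1i3 (0.12) and Cyp8b1 (-0.49) did not pass. Nr1i3 was -0.06 without control mouse 3 and -0.01 without scaling between arrays, and Cyp8b1 was 0.15 without phenobarbital mouse 3.

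In this set 31 of 13081 genes passed (limma), 30 higher and 1 lower. The lower one was E430018J23Rik (-1.81, adjusted p = 0.0362), a clone name outside the rule for named genes, given after its value was seen. The count was 11, 14 and 18 without control mouse 1, 2 and 3, 141 without phenobarbital mouse 1 (82 higher and 59 lower), and 14 and 18 without phenobarbital mouse 2 and 3. Cyp2b10, Cyp2c55, Blm and Gstm3 passed whichever mouse was left out. Por lost the call without control mouse 1 (adjusted p = 0.0552), and Cyp3a44 without control mouse 1 or 3 or phenobarbital mouse 2 (up to 0.0962). Gadd45b lost it without control mouse 1 or 2 or phenobarbital mouse 2 or 3 (up to 0.112), and Orm3 (up to 0.166) and Cyp2c37 (up to 0.116) without any mouse but phenobarbital mouse 1. The stricter filter, which needs both groups above background, gave 84 genes (73 higher and 11 lower), and normexp with quantile normalization gave 160 (128 higher and 32 lower). The count was 15 with the slide row as a block, 4 with the mouse number as a block and 7 without a filter.

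Whether the input changed the response to phenobarbital was tested on the difference between the inputs within each mouse. The genes with the smallest p were Blm (log2 3.54 at 1.5X and 2.01 at 1X, difference 1.53, SE 0.22, adjusted p = 0.548) and the long non-coding RNA gene Fendrr (difference 1.18, adjusted p = 0.672). None of the control arrays held Blm well above background, so its fold changes have only lower bounds (at least 2.78-fold at 1.5X and 3.86-fold at 1X) and their difference is not a measured one. The retinol dehydrogenase Rdh1 (-1.53), Arhgef15 (-1.18) and Dnajc19 (-1.18) followed, with the same adjusted p as Fendrr. None of 12883 genes passed (limma), and 735 had an unadjusted p under 0.05. On data simulated with a 4-fold difference the test found 79.5% of changed genes, and with a 2-fold difference 0%. The fold changes at the inputs correlated across genes with r = 0.70, against 0.44 simulated with no effect, since all mice were shared. Their covariance was 0.140 against 0.0461 simulated. Of 21 genes higher at 1X and 29 at 1.5X among those tested in both, 14 were shared, where independent lists of this size share 0.0473. Part of this may come from the shared mice, and 3 mice per group are too few to split.

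Two-colour arrays at 1X input measured a phenobarbital and a control liver on each array. The SEs and adjusted p in this paragraph use the mouse numbers of the description. Lcn2, an iron-sequestering acute phase protein, had the largest fitted increase, a log2 of 2.69 (SE 0.14, adjusted p = 5.81e-05), followed by Gstm3 (2.59, SE 0.14, adjusted p = 5.81e-05) and Cyp2c55 (2.53, SE 0.16, adjusted p = 0.000122). Gstt3 rose by 2.50 (SE 0.08, adjusted p = 5.91e-06) and the acute phase gene Saa1 by 2.21 (SE 0.26, adjusted p = 0.00312). Lower genes were Hectd2, a ubiquitin ligase (-1.22, SE 0.11, adjusted p = 0.00114), the pseudogene Serpina4-ps1 (-1.09), Socs2, an inhibitor of growth hormone signalling, which fell by 1.00, Ccdc169 (-0.97) and Saa4 (-0.96). Of the panel, Por (1.74, adjusted p = 7.56e-05), Cyp2b10 (1.72, adjusted p = 0.00803, at least 3.20-fold), Alas1 (1.47), Cyp3a11 (1.12), Aldh1a1 (1.05) and Gadd45b (1.00) rose. Cyp2b10 has only this lower bound, so its rank beside Lcn2 is unknown. Cyp2c29 (0.99), Ephx1 (0.86), Cyp2c37 (0.72) and Cyp1a2 (0.59) rose as well, while Nr1i3 (0.06) and Cyp8b1 (-0.04) did not pass. Cyp8b1 was 0.04 without control mouse 1 and 0.13 without phenobarbital mouse 3.

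The labels number the mice of these arrays in 2 ways that conflict on several arrays, although the exposures match. With the mouse numbers of the description 517 of 8258 genes passed (limma), 277 higher and 240 lower. With those of the channel source names 100 passed, 82 higher and 18 lower, all of them among the 517, with identical fold changes. Deviations of single mice on the one-colour 1X arrays went with the source names (mean r 0.527 against 0.350 with the description). The calls made only with the description are therefore the less certain ones. Lcn2, Gstm3, Cyp2c55, Gstt3, Por, Cyp2b10, Cyp3a11, Aldh1a1, Gadd45b, Ccdc169 and Saa4 passed with both. Their adjusted p was higher with the source names (limma): 0.0259 for Lcn2 (SE 0.42 in place of 0.14), 0.000257 for Gstm3, 0.000958 for Por and 0.0258 for Cyp2b10. The smaller values with the description may overstate the precision. Saa1 (adjusted p = 0.186 with the source names), Hectd2 (0.0534), Serpina4-ps1 (0.111), Socs2 (0.297), Alas1 (0.0845), Cyp2c29 (0.0535), Ephx1 (0.118), Cyp2c37 (0.116) and Cyp1a2 (0.0987) passed only with the description. Without control mouse 1, 2 and 3 the count with the description was 319, 255 and 214, and without phenobarbital mouse 1 and 2 it was 254 and 245. Cyp2c29 (up to 0.0633), Ephx1 (up to 0.0984) and Cyp2c37 (up to 0.139) then lost the call in 4, 4 and 5 of the 6 cases, Cyp2c29 and Ephx1 keeping it without control mouse 1 and phenobarbital mouse 3. Cyp2c37 kept it only without phenobarbital mouse 3. Arrays 4 and 8, whose description and channel labels give opposite dyes, were left out, and including them gave 84 genes with the channel labels and 0 with the description. Their log ratios argue against the dyes of the description. The series matrix values gave 291, and the Cy3 channel alone, an alternative chosen after the data were seen, 15.

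The gene lists of the two-colour 1X set are given with the description and, in brackets, with the source names. Among 23 CAR and PXR targets 20 rose and 1 fell [13 and 0], with a median of 1.02. Among 29 phase II enzymes 12 rose and 1 fell [9 and 0], and among 7 cell cycle genes 6 rose [3], with Birc5 at 1.15 and Cdc20 at 0.86. Among 21 acute phase genes 9 rose and 1 fell [3 and 1], and among 19 cholesterol synthesis genes 5 rose [1]. Among 15 male-biased genes 1 rose and 5 fell [0 and 0], Hsd3b5 (-0.71) and Mup21 (-0.71) lowest. Among 20 PPAR alpha and fatty acid oxidation genes 3 fell [1], with Acot1 at -0.66. Adjusted over the list alone, with the description, 21 CAR and PXR targets, 15 phase II enzymes, 7 cell cycle genes and 10 acute phase genes rose. The adjusted p of these lists (limma camera) was 6.39e-23, 1.17e-07, 6.31e-09 and 1.99e-05, also with the description. It was not computed with the source names. With the description and an estimated correlation it was an adjusted p = 0.112, 0.112, 0.0952 and 0.308.

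At 1.5X input in the two-colour format, Gstm3 had the smallest p, with a log2 fold change of 1.32 (SE 0.21, adjusted p = 0.943). Alb, which encodes albumin (-1.25), the acute phase gene Saa2 (1.06), Cyp2c38 (0.53) and the histone gene H2ac22 (0.60) followed, with an adjusted p of 0.999 each. Cyp3a11 had 0.72, Por 0.60 and Aldh1a1 0.50, none passing, and the other panel genes, Cyp2b10 among them, were not tested. None of 1662 genes passed (limma), and 28 had an unadjusted p under 0.05. Few genes were tested because the Cy5 channel had 4.73% of probes well above background. With the Cy3 channel alone, an alternative chosen after the data were examined, 9 of 15580 genes passed. On data simulated for this set the test found 44.5% of genes changed 2-fold and 83.0% of those changed 4-fold.

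Between the inputs of the two-colour format, Gstt3 had the smallest p, with a log2 of 0.75 at 1.5X and 2.50 at 1X (difference -1.75, SE 0.22, adjusted p = 0.101). Por had a difference of -1.13 (adjusted p = 0.199) and Gstm3 of -1.27 (adjusted p = 0.247). Acot3, an acyl-CoA thioesterase (1.20), and the kinase gene Ulk3 (-0.88) completed the 5 smallest p. None of 1520 genes passed (limma), and 109 had an unadjusted p under 0.05. Without a filter on dim probes 58 passed. Fold changes of both sets correlated across genes with r = 0.63, against 0.37 simulated with no effect, with a covariance of 0.0954 against 0.0296. The draws used the description's mice at 1X and were not repeated with the source names, so the simulated values may be too low.

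The array formats were compared at the same input within each mouse. At 1X, the fitted log2 values of Cyp2b10 were 1.72 on two-colour and 5.98 on one-colour arrays (difference -4.25, SE 0.39, adjusted p = 0.0107). None of its control arrays were well above background in either format. Its increases were therefore at least 3.20-fold on two-colour and at least 30.8-fold on one-colour arrays, which does not show which response was larger. The probe A_55_P2071906, which has no gene name here, had 2.04 against 4.71 (difference -2.67, SE 0.24, adjusted p = 0.0107), with 1 of 6 control arrays above background on two-colour and 2 of 3 on one-colour arrays. These 2 of 8253 genes passed (limma), and 396 had an unadjusted p under 0.05. Without phenobarbital mouse 1 or 3 none passed, without phenobarbital mouse 2 the count was 1, and with the alternative normalization of each format it was 0. The count was also 1 with the mouse number as a block and 1 without a filter on dim probes. With the source-name mice, a test chosen after the result was seen, it was 4.

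Across genes the fold changes of the formats at 1X correlated with r = 0.69, against 0.34 simulated with no effect, and the covariance was 0.0720 against 0.0147. Draws that involve the two-colour 1X set used the description's mice. Deviations of single mice correlated less between the formats with these than with the source names (mean r 0.350 against 0.527). The simulated values with this set may therefore be too low. All 14 genes higher in the one-colour set among those tested in both were also higher in the two-colour set, where independent lists share 0.470, and 13 of the 14 with the source-name mice. Both formats measured the same mice, so part of this overlap may come from the shared mice. Of the 90 genes from both one-colour inputs, 57 were tested in the two-colour 1X set, all 57 with the same sign, and 55 passed there with the description's mice and 47 with the source-name mice. Cdc20 (adjusted p = 0.0849) and Cyp2c37 (0.116) were among those that passed only with the description. The median absolute log2 of the 57 genes, which were picked by their one-colour result, was 1.46 on one-colour and 0.97 on two-colour arrays. At 1.5X, Por (0.60 against 2.35, difference -1.75, SE 0.23, adjusted p = 0.161), Gstt3 (-1.95, adjusted p = 0.161) and Gstm3 (-1.71, adjusted p = 0.371) had the smallest p. Cyp2c38 (-1.18) and the pseudogene Zfp133-ps (1.10) followed. None of 1628 genes passed (limma), and 58 had an unadjusted p under 0.05. Without a filter on dim probes 7 passed. The fold changes correlated across genes with r = 0.76, against 0.39 simulated, with a covariance of 0.132 against 0.0470. Across format and input together, one-colour 1X and two-colour 1.5X correlated below the simulated value, at r = 0.59 against 0.76, with a covariance of 0.0748 against 0.152. One-colour 1.5X and two-colour 1X had r = 0.83 against 0.55, with a covariance of 0.0990 against 0.0204.

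**Figure D3:**
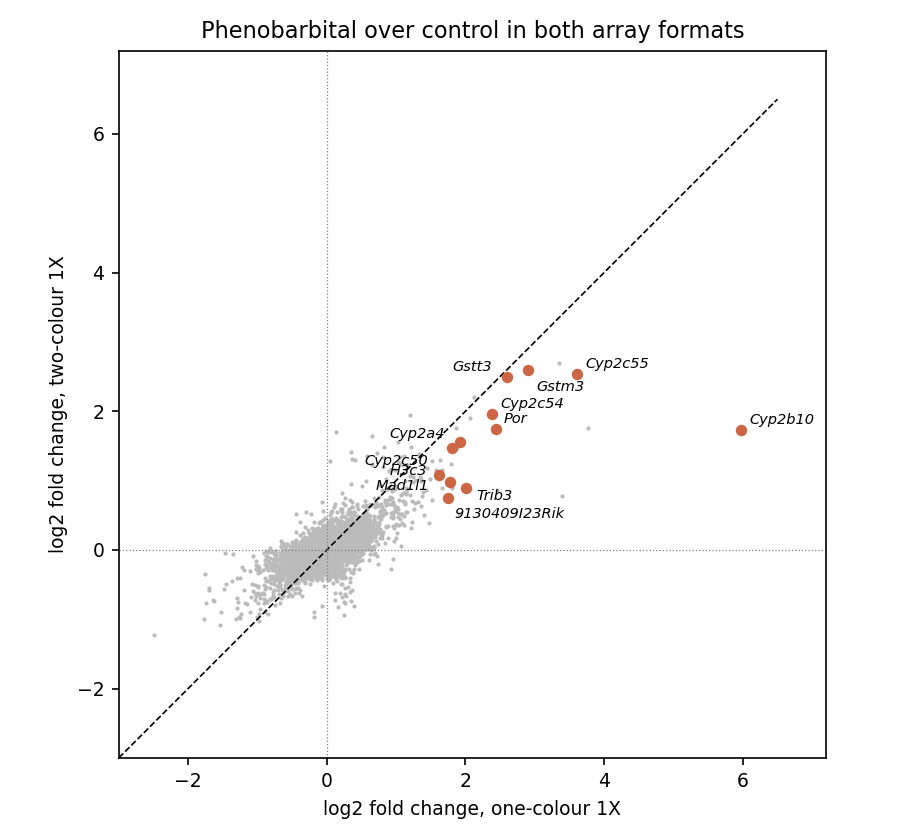
Log2 fold change (phenobarbital over control) of 5654 named genes at 1X input, one-colour arrays on the x axis and two-colour arrays on the y axis; the 12 genes past the threshold in the one-colour set are coloured and the dashed line marks equal values. By its fitted values Cyp2b10 lies furthest below the line, at 5.98 and 1.72. No control array held it well above background in either format, so these values do not show which response was larger.

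Signals of many genes, relative to each array's scale, differed between the 1.5X and the 1X one-colour arrays. Hes1, a transcriptional repressor of the Notch pathway (log2 3.10, SE 0.25, at least 3.93-fold), Sarnp, an RNA export factor (3.01), the phosphatase Ptpra (2.37), the cyclin gene Ccnj (2.33, at least 3.62-fold) and the adhesion molecule Nectin2 (2.26) had the highest fitted values at 1.5X. The major urinary protein genes Mup6 (-5.93, SE 0.10) and Mup4 (-4.76), Gal3st3, a sulfotransferase (-5.33, at least 10.4-fold lower), Mpped1 (-4.91, at least 9.26-fold lower) and the olfactory receptor Olfr1410 (-4.66) had the lowest. In total 10954 of 16689 genes passed (limma), 4217 higher and 6737 lower at 1.5X, and 5902 differed by a log2 of at least 1. Of 42 oxidative phosphorylation genes 21 were higher and 1 lower, of 23 cholesterol synthesis genes 13 and 2, and of 15 housekeeping genes 10 and 0. These lists had the same counts adjusted over the list alone. Their adjusted p was 4.13e-05, 0.00231 and 0.00133, and with an estimated correlation it was an adjusted p = 0.425 for each. Each input was 1 slide scanned in its own session, so input and slide cannot be told apart. The direction depended on the processing: normexp with quantile normalization gave 5506 higher and 5745 lower, no filter 12476 and 9102, and the stricter filter 4156 and 2611.

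The share of probes well above background was lower at 1.5X than at 1X in 6 of 6 mice. The mean difference was -15.1 percentage points (SD 4.53, n = 6 mice; exact sign-flip permutation test, two-sided, p = 0.03125, the smallest this design allows). The median signal of the negative control spots was 241 at 1.5X against 71.1 at 1X. On two-colour arrays the Cy3 share ran the other way, 26.8% at 1X and 39.4% at 1.5X, with negative controls of 91.8 and 80.6. In both formats the higher Cy3 share belonged to the slide of scan session 1, so an effect of the input was not shown. Control and phenobarbital arrays had 49.0% and 47.0% at 1X (exact permutation p = 0.5) and 33.4% and 32.5% at 1.5X (exact permutation p = 0.8, two-sided), where 3 mice against 3 allow 0.1 at the least.

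**Figure D4:**
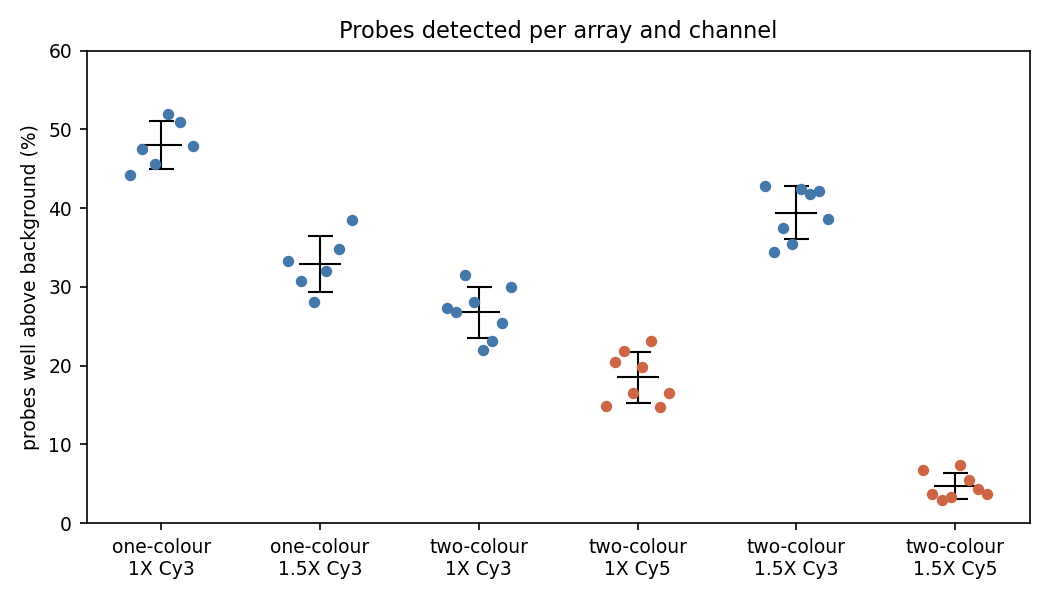
Percent of probes well above background on each array and channel, by array format and cDNA input; bars show the mean ± SD. One-colour arrays have 48.0% at 1X and 32.9% at 1.5X, and the Cy5 channel of the two-colour 1.5X arrays 4.73%.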

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

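Chosen after the result was seen were the tests of the description's mouse numbers, of the background offset and of the number of arrays per mouse in the two-colour 1X set (with either mouse numbering), of too few genes with the source-name mice, the splits of the mice in each comparison of exposure, and the source-name mice in the comparison of formats.

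The fitted values of Cyp2b10 differed between formats at 1X by a log2 of -4.25, and those of the probe A_55_P2071906 by -2.67, both past the threshold of the test of the difference. No control array held Cyp2b10 well above background in either format, so only lower bounds of its 2 increases can be given and no difference in response is shown. Another of the 10 splits of the 6 mice gave more genes in that test, 50 against the real 2. That split, control mice 1 and 3 with phenobarbital mouse 2, gave 0 genes with the source-name mice, so the 50 depend on the mouse numbering. The count therefore does not point to a structure of the samples apart from the mouse numbering. How the numbering gives it was not tested further. With the description's mice, as many genes as the real split were found in 2 of the 10 splits, the real one included, which are too few for a share under 0.05. With the source-name mice the real split gave 4 genes and each other split 0.

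Log ratios of the left-out two-colour 1X arrays were set beside those of the used arrays. Array 4 correlated across probes with a mean r of 0.628 with the 3 used arrays labelled with phenobarbital in Cy5 and -0.358 with the 3 in Cy3. Array 8 had -0.187 and 0.528. The channel labels put phenobarbital in Cy5 on array 4 and in Cy3 on array 8. The values therefore argue against the dyes of the description on both arrays. Among the two-colour 1.5X arrays with phenobarbital in Cy5, 1 array stood apart in its share of Cy3 probes well above background (gap over range 0.844). This was 1 of 8 such tests, and chance gives about 1 in 20.

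In the two-colour 1X set 517 genes passed, against 30 in the one-colour 1X set. With the description's mice the scanner's processed signals, which use no offset, still gave 473 genes. For the count with that numbering this argues against compression by the background offset. The test was not repeated with the source-name mice, so it does not cover the count with those. The spread of one-colour values averaged over 2 arrays per mouse stayed 2.14 times that of the two-colour set, with bounds set when the values were known and averages that span both inputs. On the 8246 genes tested in both it was 1.81, and at least 1.58 with 1 mouse left out. The formats were processed in different ways, so the ratio may also hold a difference in scale. For the 57 genes called over both one-colour inputs and tested there, fold changes were smaller on two-colour arrays too, with a median absolute log2 of 0.97 against 1.46. These genes were picked by their one-colour result, and only the two-colour values had the offset. Their values therefore do not show a smaller response in that format. With the description's mice the ratio therefore cannot decide on the second array. With the source-name mice the ratio was 1.61, and 1.35 on the genes tested in both, under the bound of 1.5, so the second array stays open. With the source-name mice the spread within groups was 1.33 times that with the description, so a candidate explanation for part of the count is that the description's numbers join RNA of different mice. The deviations of each mouse correlated with those on one-colour 1X arrays at a mean r of 0.527 with the source names and 0.350 with the description, a difference of 0.177, which argues against an error in the source names instead. For control mice 2 and 3 and phenobarbital mice 1 and 2, r was 0.510, 0.668, 0.631 and 0.260 with the source names. With the description it was 0.232, 0.397, 0.472 and -0.095 in the same order. These values argue against the description's numbers for these mice. No biological explanation was tested, since the mice are the same.

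No gene passed in the two-colour 1.5X set. Among the 1520 genes tested in both two-colour sets, 81 passed at 1X with the description's mice in a fit of these genes alone (136 in the fit of all genes), which alone argues against too few genes tested. With the source-name mice 10 passed in the same restricted fit, between the bounds of 5 and 20, so too few genes tested stays open. The Cy3 channel alone gave 9 genes, between the bounds of 10 and 5 set beforehand, so the dim Cy5 channel may or may not account for the missing calls and cannot be told apart from the input and the slide. These 9 included Cyp2c55 (2.12), Cyp3a44 (2.23), Cyp2a4 (1.72), Gstt3 (1.70), Cyp2c54 (1.69) and Ube2c (1.53).

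Cell cycle genes lay higher with phenobarbital in the one-colour arrays. Leaving out 1 phenobarbital mouse kept at least 0.889 of the list's median, which argues against 1 mouse setting it. RNA from immune cells stays open: the median of T, B and NK cell genes was 0.499 of that of the cell cycle list, just under the bound of 0.5 set beforehand. That list has only 4 members, Gzma (0.99), Ccl5 (0.79), Nkg7 (0.20) and Ncr1 (-0.48), so the ratio was not taken as decisive; the minimum of 5 members behind this was added after the value was seen. A response of hepatocytes to phenobarbital, the exposure the design names, stays open and was not tested.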

How the results depend on the processing

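Chosen after the result was seen were the Cy3 channel alone and the source-name mice in the comparison of formats and of two-colour inputs; the others were not. Of 144 alternative counts and shares 86 stayed on their side of the threshold or within 1.5 times, of 192 list directions 172 kept their call and 20 lost it, and of 1452 values of named genes 1210 were unchanged in direction and call, 221 lost a call, 11 gained one and 10 turned. The number of lists that passed was 16 in the main fit. It was 13 with the stricter filter, 15 with the series matrix values and 17 with normexp and quantile normalization. Unless construction is named, the cause was not tested. Without a filter on dim probes counts went both ways: they were 7 (one-colour 1X), 7 (one-colour 1.5X), 28 (both inputs), 21578 (inputs compared), 58 (difference of two-colour inputs), 1 (formats at 1X), 7 (formats at 1.5X) and 587 (two-colour 1X). The stricter filter, which tests fewer genes, gave 84 at one-colour 1.5X and 6767 between inputs. Normexp with quantile normalization gave 160 at one-colour 1.5X and 145 over both inputs, and the alternative normalization of each format 0 between formats at 1X. The series matrix values gave 18 at one-colour 1X, 59 over both inputs and 291 in the two-colour 1X set. The slide row as a block gave 11 at one-colour 1X and 15 at 1.5X.

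In the two-colour 1X set the source-name mice gave 100 genes, arrays 4 and 8 included gave 84 with the dyes of the channel labels and 0 with those of the description, and the Cy3 channel alone, which has other genes tested, 15. The log ratios of arrays 4 and 8 argue against the dyes of the description. The Cy3 channel alone gave 9 genes at two-colour 1.5X, where the other alternatives run gave 0. The source-name mice gave 4 between formats at 1X.

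With 1 mouse left out, which leaves fewer arrays, counts ranged from 5 to 18 (one-colour 1X), 11 to 141 (one-colour 1.5X), 16 to 101 (both inputs), 214 to 628 (two-colour 1X), 0 to 2 (formats at 1X) and 10004 to 10631 (inputs). The share of probes well above background differed by -16.3 to -14.1 points, with an exact permutation p of 0.0625, the smallest that 5 mice allow.

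The control and phenobarbital mice share only numbers. The deviations of same-numbered mice correlated at 0.03, -0.11 and 0.27 at one-colour 1X, and 2 of the 3 control mice there correlated best with the phenobarbital mouse of their number. The replicate block gave 3 genes at one-colour 1X, 4 at 1.5X, 36 over both inputs and 1 between formats at 1X, and changed no other count by over 1.5 times.

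Values that turned were those of Cyp8b1 and Nr1i3, neither past the threshold. With 1 mouse left out, Cyp8b1 ranged from -0.36 to 0.23 at one-colour 1X, -0.82 to 0.15 at one-colour 1.5X, -0.57 to 0.12 over both inputs and -0.12 to 0.13 at two-colour 1X, and Nr1i3 from -0.06 to 0.25 at one-colour 1.5X. Positive values of Cyp8b1 came without control mouse 2 (0.23) or phenobarbital mouse 3 (0.08) at one-colour 1X, and without phenobarbital mouse 3 at 1.5X (0.15) and over both inputs (0.12). At two-colour 1X they came without control mouse 1 (0.04) or phenobarbital mouse 3 (0.13), and Cyp8b1 was 0.02 (0.0199) from log ratios with a dye term. Nr1i3 was -0.06 (-0.0555) without control mouse 3 and -0.01 (-0.0130) with the series matrix values at one-colour 1.5X, and -0.04 (-0.0390) from 3 matched pairs at two-colour 1X.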

Other observations

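Chosen after the result was seen were the histone genes, the list means per mouse and the splits of the mice in the comparisons of exposure; the splits for the inputs and the gene lists were planned.

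Genes of linker and core histones, which package DNA, were picked by their names and looked at without a test of the group. Over both one-colour inputs 7 of 35 rose and none fell, with 31 positive and a median log2 of 0.84 (-0.51 to 1.93). In the two-colour 1X set 18 of 24 rose (11 with the source-name mice), with a median of 0.76. At one-colour 1X 1 of 39 rose (limma), at one-colour 1.5X 0 of 35 and at two-colour 1.5X 0 of 9, with medians of 0.83, 0.95 and 0.52. Many of the core histone genes are near-identical copies, so the probes do not count as independent genes.

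Some gene groups varied between the mice of a group. The genes of adipose tissue, muscle and pancreas had mean log2 deviations at one-colour 1X of -0.73, 0.52 and 1.18 in control mice 1, 2 and 3 and -1.06, -0.51 and 0.60 in phenobarbital mice 1, 2 and 3. At 1.5X they were -1.04, 0.76, 1.46, -1.35, -0.60 and 0.77 in the same order. Acute phase genes stood highest in phenobarbital mouse 2 (0.87 at 1X and 0.92 at 1.5X) and lowest in control mouse 2 (-0.58 and -0.77), while phenobarbital mouse 1 had -0.08 and -0.05. Each phenobarbital mouse stood above each control mouse for these genes at 1X. The neutrophil genes tested were highest and lowest in the same mice on one-colour arrays (0.68 and -0.61 at 1X). On two-colour 1X arrays, with 2 such genes tested, phenobarbital mouse 2 was lowest (-0.20 with the description and -0.18 with the source names) and control mouse 2 had 0.06 and -0.01. In the two-colour 1X set, acute phase genes had 0.82 in phenobarbital mouse 2 and -0.06 in mouse 1 with the source names, and 0.37 and 0.38 with the description.

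Pairs of two-colour 1X arrays that the source names number as repeats, 3 with 8 and 4 with 7, had log ratios that correlated across probes at 0.890 and 0.881. The 10 other pairs with the same dye labels ranged from 0.316 to 0.736. At two-colour 1.5X, arrays with opposite dye labels correlated at a mean r of 0.762 and those with the same at 0.821, against -0.287 and 0.523 at 1X.

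Other splits of the 6 mice into groups of 3 were counted for each comparison. For 3 mice against 3 there are 10 splits, too few for a share under 0.05. The real split stood alone (1 of 10) in 4 comparisons: one-colour 1X (30 genes, highest other 0), 1.5X (31 and 0), both inputs (90 and 0) and two-colour 1X (517 and 31). With the source-name mice the last was 100 and 29. At two-colour 1.5X and for the differences between inputs in both formats, all 10 splits gave 0. For the formats at 1.5X the real count was 0 and all 10 splits reached it, the highest of the others 16, for control mice 1 and 3 with phenobarbital mouse 1. Such a count may come from a structure of the samples or from chance, and its cause was not tested. For the gene lists 2 of 10 splits gave as many lists, 16 for the real one and 17 for the highest other. For the inputs compared within mice, 1 of 32 sign patterns gave as many genes (10954 against at most 0), a share under 0.05. Each input was 1 slide, so a swap in some mice puts the slide difference within the groups. The patterns argue against chance only for a difference between the slides. They cannot decide on the input.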
